A study of Mus musculus with 6 samples.

How the data were processed

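RNA was measured in 6 femur libraries of 12-week C57BL/6 mice labelled WT, 3 from control and 3 from phlebotomy (blood removal). Per the labels' protocols, bone fractions enriched for osteocytes (the cells embedded in bone matrix) gave the total RNA, libraries were made with Nextera XT, a kit that does not mark strand, and reads were 126 bp in paired-end mode on a HiSeq1500. The submitters' processing notes name STAR 2.7.3a, STAR 2.5.2a, DESeq2, edgeR and limma and the builds GRCm38.p3 and mm10, without saying which step used which. The counting program and its strand setting are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart.

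The authors deposited raw gene counts, a filtered copy of the same counts and a table of scaled values. The count table has 55440 rows, of which 55421 name Ensembl genes and 19 name transgene or vector sequences. The filtered copy has 28533 rows: every row kept reaches at least 6 counts in a library, every row left out has at most 5, and 0 counts differ between the tables. The deposited signal table holds, per the file's name, CPM values (counts scaled to library size) adjusted by the authors with TMM. Each of its columns is the filtered count column times a constant, with TMM factors from 0.883 to 1.145. The rows that name no mouse gene held 0.00278% to 0.0285% of counts and stayed out of library sizes and tests.

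The deposited columns carry an initial and a number. Columns starting with P were taken as phlebotomy by that initial and columns starting with N as control by elimination, which is a limit on every comparison. The column numbers are 1, 2 and 4 and the titles run from 1 to 3, so columns were tied to groups and not to single samples, and libraries are called control 1, 2 and 4 and phlebotomy 1, 2 and 4 by column number. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries.

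Libraries held 11219243 to 19015588 gene counts, so that 3 counts correspond to 0.158 to 0.267 CPM. Counting intervals cover counting error only, because reads without molecular identifiers are not independent molecules. No library pair agreed within sampling noise. Gene names came from the deposited scaled table and the reference names, and coordinates (GRCm38), transcript length and GC content from GENCODE M21, in which 99.7% of the gene IDs were found.

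Genes were filtered with filterByExpr at a minimum count of 10, which left 18838, scaled with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, robust and without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) of log2 fold changes were approximated from the F statistic. Levels are TMM-scaled CPM, as mean ± SD of 3 libraries. Gene lists (29, with 446 members named and 414 tested) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. The self-test drew counts from the real means, dispersions and library sizes with 200 genes changed, and 18256 genes of the draw passed the filter. edgeR recovered 44% of the 100 genes changed 2-fold and 87% of the 100 changed 4-fold, with 9 false calls among 140. None of 5 unchanged lists passed camera, but each gene was drawn independently, so the draw cannot test the preset correlation. The recovered shares likewise leave out variation that the genes of a library have in common, and may not hold for the real libraries. In the real lists the estimated correlation ran from -0.026 (T and NK cell) to 0.93 (ribosomal protein).

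The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Erfe; the 10 genes per direction with the largest change among those past the threshold, with at least 5 CPM in the higher group and groups that do not overlap, filled up by smallest p; up to 4 members of each list by smallest p; and 15 genes of the question. Predicted and clone-type names are counted but not named, and some genes that the rule covers are not reported here. Alternatives were other scaling, other filters on low counts, DESeq2 1.42.0, limma-voom, limma-trend on the deposited values with pseudocounts of 0.5 and 1, a replicate block, and leaving out each library in turn. Removal of a GC and length trend, protein-coding genes only, dispersion without the robust option, 5 further gene lists and a repeat of the intervals of the cell type medians without each library and with the trend removed, and comparisons of list levels over libraries were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.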

Results

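Transcript counts were compared between 3 femur libraries of control mice and 3 of mice after phlebotomy, to ask how the osteocyte-enriched transcriptome of bone differs after blood loss. The series title names erythroferrone, a secreted hormone that lowers hepcidin, the regulator of iron release. The total of gene counts was 11219243, 19015588 and 15156899 in control 1, 2 and 4, and 15866385, 15070173 and 14853290 in phlebotomy 1, 2 and 4. Groups follow the initials of the deposited column names, as described above. Dmp1, an osteocyte matrix protein, reached 34360 ± 13530 CPM in control libraries (SD, n = 3).

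Erfe, the gene for erythroferrone (ENSMUSG00000047443, protein-coding, chromosome 1, 91366430 to 91374217 on GRCm38), rose after phlebotomy. Its level was 0.592, 0.0547 and 0.134 CPM in control 1, 2 and 4 and 4.19, 4.69 and 4.68 CPM in phlebotomy 1, 2 and 4. The log2 fold change was 4.33 ± 0.52 (SE), with an edgeR adjusted p of 0.00641, and all phlebotomy libraries lay above all controls. The libraries held 9 counts in control and 216 after phlebotomy, a ratio of 21.7 with a 95% exact counting interval of 11.2 to 48.1. Control 1 held 6 of the 9 control counts, and the log2 fold change was 5.51 ± 0.55 without it and 3.71 ± 0.54 without control 2 (SE, edgeR adjusted p 0.000442 and 0.0154). Without phlebotomy 1 the log2 fold change was 4.40 ± 0.60 and the edgeR adjusted p 0.199, and limma-voom gave 4.51 with an adjusted p of 0.123; the range of adjusted p over 20 alternatives was 2.41e-14 to 0.199. DESeq2 gave a log2 fold change of 4.38 for Erfe at an unadjusted p of 4.22e-13 and no adjusted p, as for 6584 genes in that fit.

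**Figure D1:**
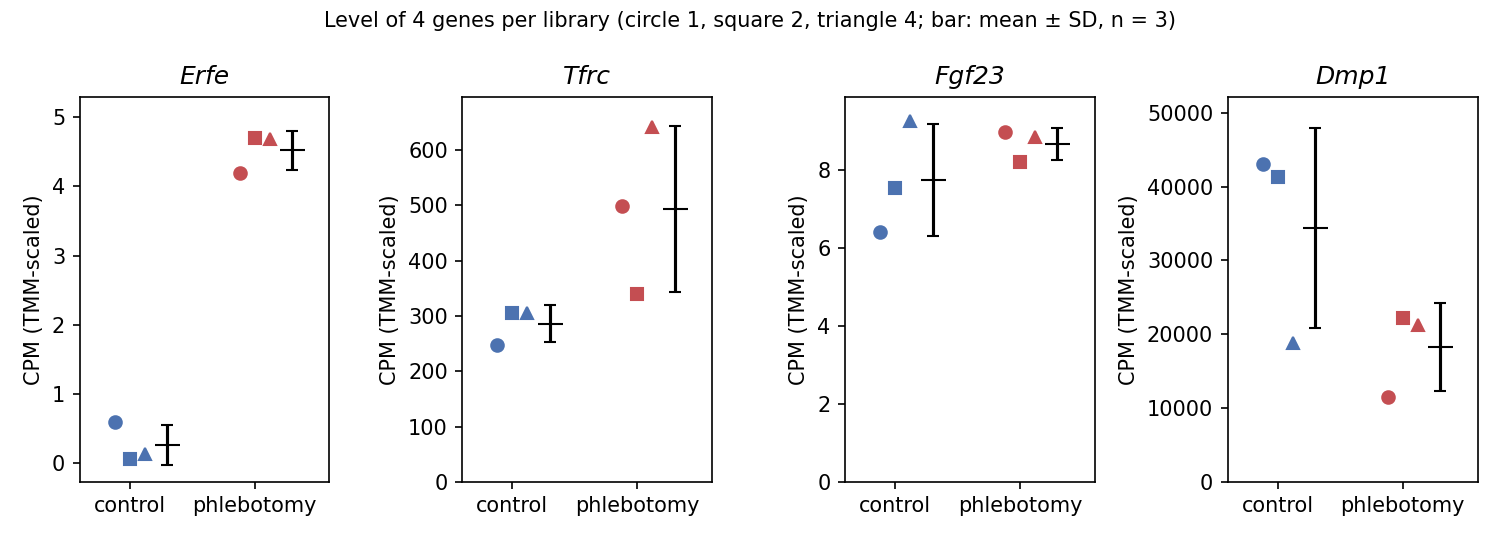
Level in TMM-scaled CPM (vertical axes, linear) of Erfe, Tfrc, Fgf23 and Dmp1 in each library, with circles, squares and triangles for libraries 1, 2 and 4 and black bars for mean ± SD of 3 libraries. Erfe lies between 4.19 and 4.69 CPM in all 3 phlebotomy libraries and at or below 0.592 CPM in controls. Fgf23 and Dmp1 overlap between groups.

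Beside Erfe, Ighv7-1 and Gm32051 rose, and 0 genes fell among the 18838 tested with edgeR. Ighv7-1, an immunoglobulin heavy-chain variable segment of a family whose near-identical members can share reads, went from 0.232 ± 0.119 to 7.35 ± 5.57 CPM (SD, n = 3; log2 fold change 4.83 ± 0.62 SE, edgeR adjusted p 0.0200). Gm32051, a predicted noncoding gene on chromosome 5 that lies outside the naming rule and was chosen after its values were seen, went from 0.307 ± 0.277 to 8.59 ± 3.50 CPM (log2 fold change 4.63 ± 0.51 SE, edgeR adjusted p 0.00558). The call of Ighv7-1 ended without control 1, 2 or 4 or phlebotomy 1 (edgeR adjusted p 0.246, 0.0641, 0.0695 and 0.0923), and that of Gm32051 without phlebotomy 1 (0.170). The log2 fold change of Ighv7-1 was 3.98 without phlebotomy 2. Other variable segments, outside the naming rule, reached 100 counts in 1 library and under 5% of that rate in every other. These were Igkv4-72 and Igkv6-13 in control 1 and Igkv1-88 and Ighv9-2 in phlebotomy 1. Such segments thus differed between single libraries of either group. Clca3a1 came next, at 6.71 ± 2.28 and 19.4 ± 0.916 CPM (edgeR adjusted p 0.0651). At an unadjusted p under 0.05 there were 1321 higher and 1774 lower genes, where chance gives 942 in all on average. Groups did not overlap for 21.3% of genes, where chance gives 10% on average. Genes move together, so a single grouping can depart from these averages without an effect of treatment. DESeq2 called 78 higher and 206 lower genes and limma-voom 0, with 2987 genes at an unadjusted p under 0.05.

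The count of changed genes rested on single libraries. It was 963 without phlebotomy 2 (356 higher and 607 lower), 14 without control 2, 7 without control 4 and 0 without phlebotomy 1 in edgeR, with 1529 genes at an unadjusted p under 0.05 in that last fit. Phlebotomy 2 lay beside the controls on the first principal component (41.8% of variance), at -7.80 against 54.9 and 40.2 for phlebotomy 1 and 4 and -51.4 to -16.6 for controls, and it also held transgene sequences described in the closing part. Its Erfe level was that of the other phlebotomy libraries.

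Genes of iron uptake and of the hepcidin axis other than Erfe did not pass over all genes in edgeR. Tfrc, the transferrin receptor, was at 286 ± 33.0 CPM in control and 493 ± 150 after phlebotomy (SD, n = 3; log2 fold change 0.79, edgeR adjusted p 0.167). Bmp2, a ligand that can induce hepcidin, was at 696 ± 165 and 369 ± 82.0 CPM (log2 fold change -0.92, edgeR adjusted p 0.139). Bmp6, Slc40a1 (the iron exporter ferroportin) and Tfr2 had log2 fold changes of -0.38, -0.43 and 0.39. With a library left out these ran from -0.63 to -0.19, from -0.56 to -0.32 and from 0.25 to 0.52. Of the 19 iron genes tested, Erfe and Tfrc were higher and Bmp2 lower when adjusted over the list alone, against Erfe alone over all genes in edgeR. Over all genes Tfrc passed higher and Bmp2 lower in DESeq2 and in edgeR without phlebotomy 2. The list median was -0.15 and its mean 0.10, and camera gave an adjusted p of 0.692. Hamp, the hepcidin gene, was not tested, with 31 counts in the 6 libraries. Fgf23, the osteocyte phosphate hormone, was at 7.74 ± 1.44 and 8.68 ± 0.414 CPM (log2 fold change 0.16 ± 0.23 SE, edgeR adjusted p 0.747).

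Bone cell genes were lower as groups. Osteocyte markers had a median log2 fold change of -0.67 with 11 of 12 members lower (camera adjusted p 3.94e-08, and adjusted p = 0.337 with an estimated correlation), and 7 were lower when adjusted over the list alone, against 0 over all genes in edgeR, where 9 were lower at an unadjusted p under 0.05. Over all genes 2 were lower in DESeq2 and 3 in edgeR without phlebotomy 2. Those lower over the list alone included Fbln7 (-1.24), Fam20c (-0.94), Dmp1 (-0.91) and Mepe (-0.72), a matrix protein of osteocytes. Dmp1 overlapped between groups, at 18770 CPM in control 4 against 22230 and 21300 CPM in phlebotomy 2 and 4. Sost, which encodes the Wnt inhibitor sclerostin, had a log2 fold change of -0.52 (edgeR adjusted p 0.303), and of -0.73 to -0.22 with a library left out. Osteoblast and bone matrix genes had a median of -0.59 with 20 of 20 lower (camera adjusted p 3.36e-10, and adjusted p = 0.349 with an estimated correlation), and 8 were lower over the list alone, Runx2 (-0.63) and Col11a2 (-1.20) among them, against 0 over all genes in edgeR, where 10 were lower at an unadjusted p under 0.05. DESeq2 called 4 of the osteoblast genes lower over all genes, and edgeR without phlebotomy 2 called 13. In phlebotomy 2 the osteoblast genes lay at 0.20 on the centred log2 scale, inside the control range of 0.13 to 0.62, against -0.77 and -0.42 in phlebotomy 1 and 4. Osteocyte markers did not overlap between groups on that scale. They lay at -0.60, -0.19 and -0.16 in phlebotomy 1, 2 and 4 and from 0.14 to 0.55 in controls. Chance alone keeps groups of 3 apart in 10% of cases. The osteoblast median was -0.33 without phlebotomy 1 and -0.95 without phlebotomy 2.

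The phosphate and FGF23 axis list (median -0.71, 12 of 15 lower, 9 over the list alone) and the remodelling and Wnt list (median -0.40, 14 of 16 lower, 2 over the list alone) were also lower, with camera adjusted p 5.89e-07 and 0.000164, and adjusted p = 0.337 with an estimated correlation for each. In the former, Ank, which raises pyrophosphate outside cells, had a log2 fold change of -1.01 and Fgfr1 of -0.75; in the latter, Lrp5, a Wnt co-receptor, had -1.24 and Csf1, a macrophage growth factor, -0.62. Tnfsf11 (RANKL) and Tnfrsf11b (osteoprotegerin) had log2 fold changes of 0.03 and -0.76, and Tnfsf11 turned negative under some alternatives. BMP response genes had a median of -0.41 with 12 of 12 lower (camera adjusted p 0.000164, and adjusted p = 0.337 with an estimated correlation), Smad6 and Smad7 being the 2 lower over the list alone. Chondrocyte genes (median -0.86, 8 of 8 lower) and periosteal genes (median -0.47, 14 of 14 lower) had camera adjusted p of 0.000394 and 2.04e-05, and adjusted p = 0.337 with an estimated correlation for each. Over the list alone, 2 members of each were lower, Sox9 and Comp in the former and Thbs2 and Col5a1 in the latter. Over all genes none of the members of these 5 lists passed in edgeR, where 10, 6, 6, 5 and 6 were lower at an unadjusted p under 0.05 in the phosphate, remodelling, BMP, chondrocyte and periosteal lists. In the same order 3, 2, 0, 1 and 2 members were lower over all genes in DESeq2, and 5, 2, 2, 1 and 2 in edgeR without phlebotomy 2. The phosphate median was -0.46 with the GC and length trend removed, the remodelling median -0.61 without phlebotomy 2, and the periosteal median -0.27 without control 1 and -0.31 without phlebotomy 1. On the centred log2 scale none of these 5 lists overlapped between groups. In the same order they lay at -0.13, -0.047, -0.086, -0.50 and -0.094 in phlebotomy 2. The lowest control levels were 0.0019, 0.030, 0.13, 0.11 and 0.068.

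Interferon-response genes were higher as a group, with a median log2 fold change of 0.96 and 16 of 16 members higher (camera adjusted p 2.23e-12, and adjusted p = 0.337 with an estimated correlation). All 16 were higher when adjusted over the list alone and at an unadjusted p under 0.05, against 0 over all genes in edgeR and 6 in DESeq2. Oas1a, an antiviral enzyme, went from 7.33 ± 1.41 to 17.0 ± 6.68 CPM (SD, n = 3), and Ifi44 (1.45) and the chemokine Cxcl10 (1.01) had the next smallest p. The centred log2 level was 1.07 and 0.55 in phlebotomy 1 and 4 and -0.27 in phlebotomy 2, with controls from -0.54 to -0.37. Without phlebotomy 2, 13 of the 16 passed over all genes in edgeR, and without phlebotomy 1 the median was 0.59.

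Immediate early genes, which respond within minutes to stimulation and handling, were lower, with a median of -0.53 and 14 of 14 members lower (camera adjusted p 5.46e-11, and adjusted p = 0.337 with an estimated correlation). Over the list alone 10 were lower, against 0 over all genes in edgeR, where 11 were lower at an unadjusted p under 0.05, 4 in DESeq2 and 6 in edgeR without phlebotomy 2. Egr1 was at 1423 ± 207 CPM in control and 694 ± 106 after phlebotomy (SD, n = 3; log2 fold change -1.03, edgeR adjusted p 0.139), and Egr2 and Fosb had log2 fold changes of -0.94 and -1.01. The centred level was -0.53 and -0.51 in phlebotomy 1 and 4 and 0.07 in phlebotomy 2, with controls from 0.24 to 0.40, and the median was -0.91 without phlebotomy 2.

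Erythroid genes, as markers of red cell precursors, had a median log2 fold change of 0.12 with 18 of 27 higher (camera adjusted p 0.00358, and adjusted p = 0.727 with an estimated correlation), and Tfrc and Car1 (0.83) were higher over the list alone, against 0 over all genes in edgeR, where 6 were higher at an unadjusted p under 0.05. Over all genes 2 erythroid genes were higher in DESeq2, and 2 in edgeR without phlebotomy 2. Without control 1, whose erythroid level of -0.76 was the lowest of the 6, the median was -0.15 and the call ended (camera adjusted p 0.386). The call also ended without phlebotomy 2 (median 0.09, camera adjusted p 0.0870). With no low-count filter and over the authors' filtered genes it ended too (medians 0.051 and 0.031, camera adjusted p at most 0.0774). The median was 0.34 without control 4 and 0.21 without phlebotomy 4. Heme synthesis genes had a median of 0.27 with 10 of 12 higher (camera adjusted p 0.00265, and adjusted p = 0.589 with an estimated correlation), and Tmem14c (0.78), a porphyrin transporter, was higher over the list alone. That call ended without control 1 (median 0.065) and without phlebotomy 2 (median 0.26). The erythropoietin and STAT5 target list, which holds Erfe and Tfrc, had a median of -0.25 and a mean of 0.17 (camera adjusted p 0.874), and Epor had a log2 fold change of -0.16. Cell cycle genes were higher in 25 of 25 members (median 0.40, camera adjusted p 1.98e-08, and adjusted p = 0.408 with an estimated correlation), with Tyms (0.77) and Ccnb1 (0.64) higher over the list alone. Their centred level was 0.23 and 0.33 in phlebotomy 1 and 4 and 0.055 in phlebotomy 2, inside the control range of -0.58 (control 1) to 0.087. Ribosomal protein genes were higher in 24 of 24 members (median 0.35, camera adjusted p 1.64e-07, and adjusted p = 0.480 with an estimated correlation), 0 of them over the list alone in edgeR, where 10 had an unadjusted p under 0.05. The ribosomal centred level was 0.53 in phlebotomy 1, -0.045 and 0.024 in phlebotomy 2 and 4, and -0.19 to -0.14 in controls. The cell cycle median was 0.20 without control 1 and the ribosomal median 0.17 without phlebotomy 1.

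**Figure D2:**
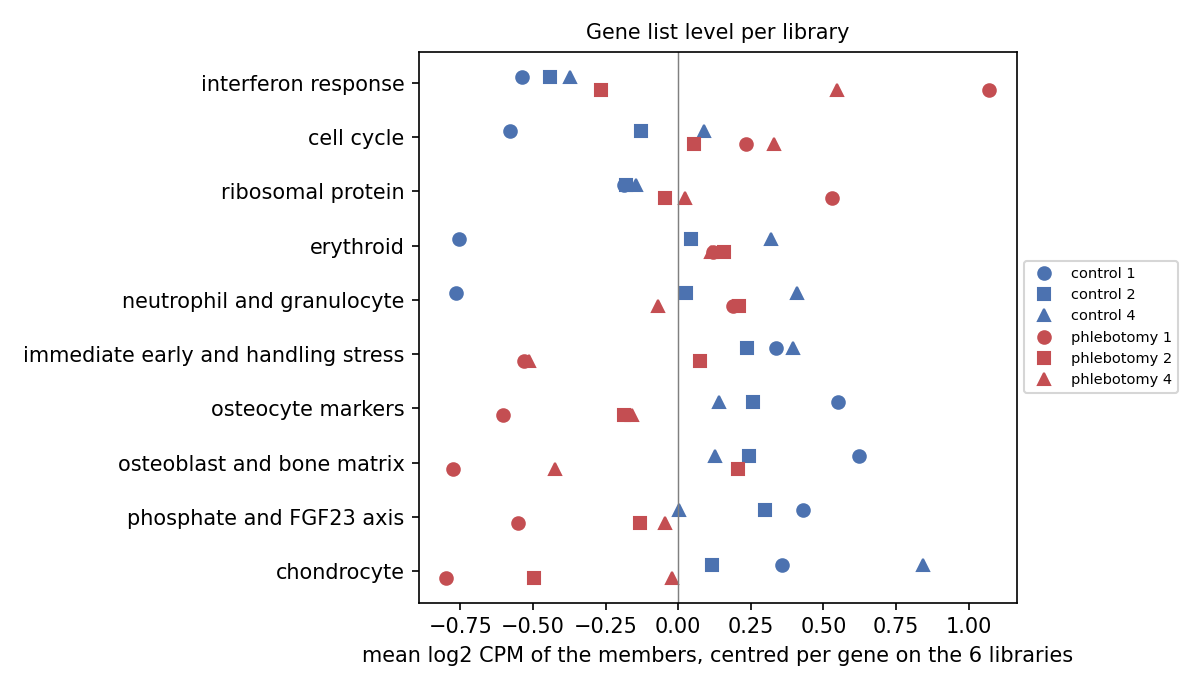
Mean log2 CPM of the members of 10 gene lists, centred per gene on the 6 libraries (horizontal axis), with blue for control, red for phlebotomy and circles, squares and triangles for libraries 1, 2 and 4. Interferon-response genes lie at 1.07 and 0.55 in phlebotomy 1 and 4 and at -0.27 in phlebotomy 2, and erythroid genes lie lowest in control 1, at -0.76.

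Neutrophil genes had a median of 0.062 with 12 of 18 higher (camera adjusted p 0.0399, and adjusted p = 0.738 with an estimated correlation), and the granule proteases Prtn3 (1.18) and Ctsg (1.25) were higher over the list alone. The neutrophil median was -0.18 without control 1, 0.43 without control 4, 0.039 and -0.077 without phlebotomy 1 and 2, and 0.15 without phlebotomy 4, and the call ended without control 1, phlebotomy 1 or phlebotomy 2, and in 4 of the 11 alternatives of scaling, filter or model, where its median ran from -0.045 to 0.18. Monocyte and macrophage genes had a median of 0.27 (camera adjusted p 0.0411, and adjusted p = 0.480 with an estimated correlation) and B-lineage genes of -0.30 (camera adjusted p 0.00577, and adjusted p = 0.480 with an estimated correlation), with 2 members lower over the list alone, Cd22 (-1.05) among them. The monocyte call ended without control 1, 2 or 4 or phlebotomy 1 or 4 (medians 0.19, 0.23, 0.30, 0.14 and 0.18) and in 2 of the 11 alternatives, and the B-lineage median was -0.53 without phlebotomy 2. In phlebotomy 2 the centred level was -0.16 for monocyte genes, the lowest of the 6 libraries, and 0.19 for B-lineage genes, inside the control range of 0.11 to 0.24. Vegfa, an angiogenic factor induced by low oxygen, was at 1304 ± 429 and 718 ± 208 CPM (SD, n = 3; edgeR adjusted p 0.191), and the hypoxia list had a median of -0.19 (camera adjusted p 0.0399, and adjusted p = 0.349 with an estimated correlation), -0.34 without phlebotomy 2 and -0.073 without phlebotomy 1, where its call ended, as it did in 5 of those 11 alternatives. With preset correlation 18 of 29 lists passed, 7 higher and 11 lower. With estimated correlation and by fry none passed over all 6 libraries, while fry's test for change in either direction called the iron and the erythropoietin lists, both of which hold Erfe. Without phlebotomy 2, fry called the immediate early list alone (adjusted p 0.0237), and none passed with an estimated correlation. Fry's either-direction test then called further lists, the endothelial (adjusted p 0.0143) and interferon (0.0421) lists among them.

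Reads over 1415 olfactory and vomeronasal receptor genes, used as a measure of background, came to 95.4, 105 and 96.3 CPM in control 1, 2 and 4 and to 213, 121 and 324 CPM in phlebotomy 1, 2 and 4. Across 12180 genes, which are not independent replicates, log2 fold changes ran with transcript length (Spearman's rho -0.374) and GC content (-0.246). Within single libraries, against the mean of the 6, the rho with length was -0.444 in phlebotomy 1, -0.00782 and -0.0522 in phlebotomy 2 and 4 and 0.105 to 0.356 in controls, and that with GC content was -0.233, 0.281 and -0.356 in phlebotomy 1, 2 and 4 and 0.0314 to 0.381 in controls. Mitochondrially encoded genes took 2.29% of counts in phlebotomy 1 and at most 1.59% in the other libraries. Genes below the lower quartile of length had a median of 0.14 and those above the upper quartile of -0.23.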

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

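The test of the size of the Erfe difference, the repeat of the cell type intervals without each library and with GC and length removed, and the comparisons of list levels over libraries were chosen after the results they bear on had been seen; the other tests here were set beforehand. With groups of 3, no library was tested as an outlier.

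Rows for transgene or vector sequences stood above the control level in phlebotomy 2, though all mice are labelled WT: Neo with 2288 counts, EGFP with 920, DsRed with 403, Venus with 75 and mLamp3 with 24, where no control library had more than 12. Only 1 mouse gene was private to this library, against 0 to 3 in the others, where at least 20 would have pointed to reads mixed in from another library and under 5 had been set to speak against it. That lower bound was wrong by design, since a bone library mixed in would bring no private genes, so mixed reads and a transgenic animal cannot be told apart. The library does not carry the Erfe call, which had an adjusted p of 0.00679 and a log2 fold change of 4.26 without it.

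Erfe was higher after phlebotomy, and cells, background and single libraries were weighed as sources. The erythroid list without Tfrc had a median of 0.11 ± 0.07 (SE over genes), below the rise above 1 that more erythroid cells would need. Its mean level differed by 0.24 ± 0.33 over libraries (SE, n = 3 per group). Background at the length of Erfe reached 0.240 CPM at most, below the Erfe level in each phlebotomy library. In control 1, 2 and 4 that background was 0.0705, 0.0774 and 0.0712 CPM, against Erfe levels of 0.592, 0.0547 and 0.134 CPM. Erfe was thus not above background in control 2, and the fold is measured against a control level near it. The test set beforehand for a single library came out for it: without phlebotomy 1 the edgeR adjusted p was 0.199, the highest of 6. The unadjusted p was 4.10e-05 in that fit, with 1529 genes under 0.05 in place of 3095. The log2 fold change was not smaller there, at 4.40 ± 0.60 (SE) against 4.33 over all libraries. No single library made the whole difference, which was 3.71 ± 0.54 (SE) without control 2 and 5.51 ± 0.55 without control 1. The size of the fold thus depends on the few control counts, 6 of 9 of them in control 1. Without phlebotomy 1 the edgeR call was lost but not the fold, and limma-voom gave no call with all libraries kept (adjusted p 0.123). Induction within residual erythroid cells may still be the source, since Klf1, an erythroid transcription factor, was at 40.3 CPM or more in each phlebotomy library, and phlebotomy acting on osteocytes stays open beside it.

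Osteoblast and bone matrix genes were lower after phlebotomy, with a median log2 fold change of -0.59 (adjusted p = 0.349 with an estimated correlation), though phlebotomy 2 lay within the control range. With the GC and length trend removed the median was -0.52 ± 0.05 (SE over genes, which are not independent), so that trend is not the whole source of the median. Over libraries, with the trend kept, the mean level differed by -0.66 ± 0.32 (SE, n = 3 per group), and the groups overlapped. Background took at most 0.902% of counts, too little to dilute the list. Phlebotomy 1 and 4, with the most background (213 and 324 CPM), also had the lowest list levels (-0.77 and -0.42). A lower share of bone cells would raise other cell types alike, and intervals (2 SE over genes) that lay apart had been set to speak against it: those of the monocyte (-0.0014 to 0.54) and endothelial (-0.43 to -0.0997) medians lay 0.0983 apart, and some pair did so in 7 of 7 further fits, by 0.0712 to 0.362. That bound was wrong by design, since it left out the spread over libraries, where the monocyte level less the endothelial one differed by 0.42 ± 0.31 (SE, n = 3 per group), phlebotomy 2 was at -0.38 against controls of -0.35 to -0.058, and the groups overlapped in 15 of 15 pairs of cell types. A lower share of bone cells, phlebotomy itself, a change within single cell types and differences in preparation therefore stay open.

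Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes, the real one with 3 against at most 2 in the others; 10 splits are too few for a share under 0.05.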

How the results depend on the processing

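The GC and length, protein-coding and robust-dispersion alternatives were chosen after seeing the data; the others were planned. DESeq2 gave Erfe no adjusted p, and Erfe stayed past the threshold in 18 of the 20 other alternatives. Its log2 fold changes ran from 2.11 on the deposited values, where a pseudocount shrinks them, to 5.51 without control 1. Erfe lost the threshold in limma-voom and without phlebotomy 1. Ighv7-1 lost it in 7 alternatives and Gm32051 in limma-voom (adjusted p 0.142) and without phlebotomy 1 (adjusted p 0.170). The count of changed genes, 3, was 577 with no filter on low counts (166 higher, 411 lower), 20 over the authors' filtered genes (6 and 14), 284 in DESeq2 (78 and 206), 0 in limma-voom, and 1 (1 higher) over protein-coding genes. The protein-coding filter leaves out Ighv7-1 and Gm32051, which are not of that class. For the other counts the cause was not tested. Leaving out 1 library gave 0 (without phlebotomy 1) to 963 (without phlebotomy 2), with 0 to 356 higher and 0 to 607 lower. Library sizes alone moved the median of all genes by 0.14. Lists past the threshold, 18, were 15 to 20 with a library left out, 16 to 19 in the 11 alternatives of scaling, filter or model and 0 with an estimated correlation and with fry. In those 11 alternatives calls ended for hypoxia (5), neutrophil (4), erythroid, monocyte and stromal lists (2 each) and were gained for endothelial (3), skeletal muscle and adipocyte (2 each) and mitochondrial genes (1), with a highest adjusted p of 0.168 for hypoxia, 0.193 for neutrophil and 0.316 for monocyte genes; the cause was not tested. With library sizes only, medians were -0.17 for B-lineage, -0.26 for remodelling, -0.28 for BMP response, -0.072 for stromal and -0.051 for hypoxia genes, and with the trend removed -0.024 for hypoxia genes. In their deviations from the group mean, same-numbered libraries correlated at -0.187, -0.107 and -0.155, which gave no sign of pairing by column number. Deviations within a group of 3 depend on each other, so these values cannot exclude a pairing. The replicate block gave 3 changed genes and 19 lists, with the endothelial list added, and changed no other call.

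Directions turned in 52 cases, 29 for lists and 23 for genes, 48 of them with the threshold passed in neither fit; directions of lists are those of camera, and the cause was not tested. With no low-count filter and over the authors' filtered genes, medians were 0.090 and 0.062 for osteoclast, -0.040 and -0.068 for inflammation and 0.025 and 0.032 for sex-linked genes, and Tnfsf11 was -0.031 and -0.062; Uty was -0.0071 over the latter. On the deposited values Tnfsf11 was -0.069 at either pseudocount. With GC and length removed, medians were -0.084 for iron, -0.095 for erythropoietin, -0.096 for inflammation and -0.25 for mitochondrial genes (adjusted p 0.00286, past the threshold as lower), and log2 fold changes -0.076 for Tnfsf11, -0.023 for Pf4, -0.083 for mt-Atp8, -0.28 for mt-Nd6, -0.27 for mt-Atp6 and -0.00097 for Eif2s3y. The erythropoietin median was -0.22 at 1 CPM in 3 libraries and -0.19 over protein-coding genes.

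With a library left out, medians of lists without a call or with a turned direction ranged from -0.16 to 0.47 (osteoclast), -0.22 to -0.100 (iron), -0.15 without control 1 to 0.34 (erythroid), -0.41 to -0.17 (erythropoietin), -0.18 without control 1 to 0.43 (neutrophil), -0.23 to -0.00017 (T and NK cell), -0.53 to 0.41 without control 4 (megakaryocyte, adjusted p 0.0235, and 0.0313 as lower without control 1), -0.10 to 0.050 (inflammation), -0.053 to 0.32 without control 1 (mitochondrial, adjusted p 0.000689), -0.51 without phlebotomy 2 to -0.061 (endothelial, adjusted p 0.00128), -0.57 without control 4 to -0.090 (adipocyte, adjusted p 0.00261), 0.12 to 0.54 without control 4 (skeletal muscle, adjusted p 0.0472) and 0.030 to 0.21 (sex-linked). Gene values ranged from -0.51 to 0.078 for Epor, -0.11 to 0.095 for Tnfsf11, -0.74 to 0.14 for Gp5, -0.025 to 0.57 for Pf4, -0.49 to 0.037 for Des, -0.025 to 0.33 for mt-Nd6, -0.079 to 0.39 for mt-Atp6 and -0.088 to 0.15 for Uty.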

Other observations

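Among further lists fixed before the data were examined, stromal genes had a median log2 fold change of -0.22 with 10 of 10 lower (camera adjusted p 0.0215, and adjusted p = 0.349 with an estimated correlation), and Pdgfrb and Foxc1 were lower over the list alone. That call ended without control 1 (median -0.12), without phlebotomy 2 (-0.26), with the GC and length trend removed (-0.12) and over protein-coding genes (-0.15), and the median was -0.37 without control 4 and -0.13 without phlebotomy 4. Osteoclast genes had a median of 0.16 (camera adjusted p 0.776), though Nfatc1, a transcription factor of osteoclast formation, was lower over the list alone at -0.90. Skeletal muscle genes had a median of 0.090 (camera adjusted p 0.0824), with Mylpf (0.94) and Myh4 (1.69) higher over the list alone. Without control 2 and without control 4 the muscle median was 0.20 and 0.54 and the list passed (camera adjusted p 0.0242 and 0.0472), and with any 1 library left out it was 0.12 or more. T and NK cell, endothelial, megakaryocyte and adipocyte genes had medians of -0.14, -0.27, -0.20 and -0.34 (camera adjusted p 0.794, 0.0638, 0.662 and 0.265). Megakaryocyte genes passed as lower without control 1 (median -0.43, camera adjusted p 0.0313) and as higher without control 4 (0.41, 0.0235). The endothelial list passed without control 2 (median -0.39, camera adjusted p 0.00838) and without phlebotomy 2 (-0.51, 0.00128), and was at -0.061 without phlebotomy 1; its centred level in phlebotomy 2 was 0.21, the highest of the 6 libraries. Adipocyte genes passed without control 4 (median -0.57, camera adjusted p 0.00261) and were at -0.090 without control 1. Inflammation, mitochondrially encoded and sex-linked genes had medians of 0.0099, 0.14 and 0.12 (camera adjusted p 0.692, 0.144 and 0.692). The mitochondrial list passed as higher without control 1 (median 0.32, camera adjusted p 0.000689) and without phlebotomy 4 (0.25, 0.0145), and as lower with the GC and length trend removed (-0.25, 0.00286). With an estimated correlation the skeletal muscle, endothelial, adipocyte, megakaryocyte and mitochondrial lists had adjusted p = 0.349, 0.693, 0.743, 0.897 and 0.845 over all 6 libraries.

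The other 5 lists were chosen after the leading genes had been seen. Interferon-gamma-induced GTPases had a median of 0.67 (camera adjusted p 3.04e-07, and adjusted p = 0.384 with an estimated correlation), with centred levels of 0.49 and 0.52 in phlebotomy 1 and 4 and of -0.21 in phlebotomy 2, inside the control range of -0.55 to -0.0025. Circadian clock output genes had a median of -0.37 (camera adjusted p 0.00203, and adjusted p = 0.307 with an estimated correlation). Unfolded protein response, immunoglobulin constant and late erythroblast genes had medians of 0.14, -0.51 and -0.21 (camera adjusted p 0.158, 0.187 and 0.158).

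A transgene row named for GNAS held 372 to 619 counts in the 6 libraries, in controls as after phlebotomy.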
